A study of Caenorhabditis elegans with 2 samples.

How the data were processed

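Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans at the third larval stage (L3), from mixed-sex populations of strain OP236. Per the labels, this strain carries the unc-119(ed3) mutation on chromosome III and the transgene wgIs236, and the immunoprecipitation was directed against ZTF-11 tagged with eGFP, an enhanced green fluorescent protein. ZTF-11 is a zinc finger transcription factor of the Myt1 family, whose members are known as repressors of non-neuronal genes during neurogenesis. The antibody field of the labels names ztf-11 itself, so the labels leave open whether an antibody to the tag or to the protein was used. The labels number 2 biological replicates of 1 group, with a library size range of 150 to 350, so the comparison the design implies is between the replicates. It is followed by a description of the authors' thresholded peaks, not all of which were found in both replicate lists. No other strain, stage or untagged sample was used here.

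The deposited files are peak lists, not reads. Per the labels' text records, the authors made 1 list from the alignments of each replicate with a control and 1 relaxed list from both replicates pooled. They derived 1 thresholded list from the pooled list and both replicate lists by the irreproducible discovery rate (IDR). This method is meant to keep peaks whose rank is repeatable. The authors' name for the thresholded list calls it optimal. Of its 96 peaks on ce11, 61 overlapped a peak in both replicate lists. It is therefore not read here as a list of peaks shared by the replicates. Each list exists on the genome builds ce10 and ce11. The peak caller, its version, the aligner, the read filters and the IDR threshold are not given in the sources used here. Each deposited peak carries a signal score from the authors' peak caller, on a scale not given in the sources used here, and a -log10 q-value, also deposited by the authors. The signal score is the authors' own value for each peak and served here to rank, filter or describe peaks within a list. Across lists it entered the correlations between the replicates and the matching of ce10 to ce11 peaks. The lists give no read numbers, so the depth of each library is unknown, and peak numbers of the replicates cannot be set against their depths.

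Peaks on ce11 were analysed with the WBcel235 assembly, the same sequence as ce11, and the Ensembl 115 gene annotation. The end of every ce11 peak lay within the chromosome lengths of that assembly. No coordinates were converted between builds, and the ce10 lists were compared by number, length and signal score only, or among themselves. Positions are 1-based. Protein-coding mitochondrial genes were named by their overlap with the RefSeq annotation of the same assembly. The 5′ end of a gene was its annotated gene start, which for trans-spliced genes can lie downstream of the start of transcription.

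The peaks of replicate 2 were called shared with replicate 1 when they overlapped by 1 bp or more, and 1000 random placements of each replicate 2 peak on its own chromosome gave the chance number. The same was done for the 96 strongest peaks of each replicate, as many as the thresholded list holds. Spearman's rho of the signal scores over overlapping peaks was tested with 100000 permutations. For the thresholded peaks, summits were placed 10000 times at random on their own chromosomes, which gave permutation p-values for the promoter share (summit within 500 bp of the 5′ end of a protein-coding gene, two-sided) and the feature classes (promoter, exon, intron, intergenic, in that order of precedence, two-sided). The same placements gave the number of peaks within 1000 bp of the 5′ end of a gene of each of 37 gene lists (one-sided, for excess). A further test drew as many genes at random from those with a 5′ end within 1000 bp of a replicate 1 peak, which is the hypergeometric distribution. Benjamini-Hochberg adjustment was applied over the feature classes, over the gene lists and over the tests of chromosome distribution, which were exact binomial tests against chromosome length. The core sequence of Myt1-family sites, AAGTTT on either strand within 100 bp of the summit, was compared with windows of equal size centred 1000 bp away on a randomly chosen side by the exact McNemar test. Peaks within 20 kb of ztf-11 and of unc-119 were counted in every list and tested against 10000 random placements. The transgene of the strain was taken to carry extra copies of sequence from these genes, which was not tested otherwise. Shares have exact Clopper-Pearson 95% confidence intervals. Tests over peaks treat positions as units, so their p-values measure the spread over positions in these libraries and not the spread between animals.

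The gene lists, tests, windows and the rule for named genes were chosen before the data were examined. The rule took the 25 thresholded peaks with the highest signal score, each named by the protein-coding gene with the nearest 5′ end. It added the genes of each list with a thresholded peak within 1000 bp (4 where a list had over 10) as well as ztf-11 and unc-119. The gene lists covered neuronal genes and neurogenesis factors, other tissues of the larva, signalling pathways, gene families and the classes of noncoding RNA. After the data were seen, nuclear peaks were also analysed alone, peaks found in both replicates were analysed alone, the gene lists were run on the pooled list, and further nuclear peaks and the contrast of X with the autosomes, with counts of GCGCAGGG, were added. Alternatives also covered the overlap that counts as shared, a stricter list, the strongest 96 peaks of each replicate alone, the windows, the background and the genome build.

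Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and blastn 2.17.0 for further copies of peak sequences. The tests were also tested on simulated peaks. Among 200 simulated sets of 73 peaks, the number of nuclear thresholded peaks, 32 of the lists were planted in turn with peaks at 5 of their genes and called in 100% of the sets, and a list was called in 1% of the sets without planting, over 37 lists. Without planting, the promoter test called 3.5% of the sets and the motif test 2%; the motif test called 99.5% of the sets with the motif planted in 30 of 96 windows. The overlap test called 2 of 20 simulated sets without planting and 20 of 20 with 30 of 300 peaks copied. It was simulated with a random sample of the replicate 1 peaks, not the full list. For the list, promoter and overlap tests, unplanted peaks came from the same uniform placement that gave the p-values. In the motif simulation, peak and flank windows shared 1 base composition. These rates therefore check the calculations, not the tests where summits and flanks differ in base composition.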

Results

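The deposited data described the binding of eGFP-tagged ZTF-11 in whole L3 larvae from 2 biological replicates of 1 group. On ce11, replicate 1 had 30000 peaks with a median width of 320 bp, and the same number on ce10. Whether its length was set by a limit on the number of peaks is not given in the sources used here, so 30000 is not read as the number of bound positions. Replicate 2 had 2036 peaks with a median width of 360 bp. The relaxed list of the pooled replicates held 631 peaks and the thresholded list 96, which were the 96 strongest of the pooled list by signal score. The thresholded peaks covered 30425 bp, with signal scores from 41.0 to 891 and -log10 q-values from 1.05 to 1.65. Of the 96 thresholded peaks, 73 lay on the nuclear chromosomes and 23 on the mitochondrial DNA.

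The 1st question was how far the replicates shared peaks. Of the 2036 replicate 2 peaks, 677 overlapped a replicate 1 peak (33.3%, 95% confidence interval 31.2 to 35.3), against a mean of 389 in random placements and at most 458. The excess was 1.74-fold, with a one-sided permutation p of 0.000999, the smallest that 1000 placements can give. Among the 96 strongest peaks of each replicate, 19 replicate 2 peaks overlapped a replicate 1 peak (19.8%, 95% confidence interval 12.4 to 29.2). The placements gave a mean of 0.052 and at most 2, with a permutation p of 0.000999. Across the 677 overlapping pairs, which are not independent replicates, Spearman's rho of the signal scores was 0.241 (permutation p = 1e-05, the smallest 100000 permutations can give) and Pearson's r of the log2 scores was 0.438. At the 66 pairs that lay at a thresholded peak, rho was 0.0318 (permutation p = 0.80). These pairs were selected by the signal of both replicates pooled, so the 2 values of rho are not directly comparable. Whether the selection lowered rho was not tested.

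All 73 nuclear thresholded peaks were found in replicate 1, at a median rank of 75 and with 60 of them among its 1000 strongest peaks. Replicate 2 held 61 of the 73 (83.6%), at a median rank of 62. The 12 nuclear peaks found in replicate 1 only included the peak in pks-1 at X 5429414 to 5429733, rank 4 in replicate 1, and those at pot-3 and cox-5B. The 23 mitochondrial peaks were found in replicate 2 and none in replicate 1, which listed 0 mitochondrial peaks; whether mitochondrial reads or peaks were filtered there is not given in the sources used here. Thus 61 of the 96 thresholded peaks were found in both replicate lists. The thresholded list was chosen from these replicates, so these numbers describe the lists and are not independent evidence of binding.

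The mitochondrial DNA, a circle of 13794 bp, held the strongest peaks of the thresholded list. All 10 strongest peaks and 20 of the strongest 25 were mitochondrial, with a median signal score of 147 over the 23 peaks against 46.9 over the 73 nuclear peaks. The strongest, at M 12325 to 12524, lay in ND5, a subunit gene of NADH dehydrogenase, with a signal score of 891 and rank 1. It was followed by a peak in ND2 at 3553 with a score of 367, one in COX1 at 8088 with 319, one in CYTB at 4503 with 302 and one in ND1 at 1693 with 294. By nearest 5′ end, the 20 mitochondrial peaks among the strongest 25 belonged to 11 genes. COX1 and COX2 were named by 3 peaks each, CYTB, ND1, ND2, ND4 and ND5 by 2 each, and ATP6, COX3, ND3 and ND4L by 1 each. Peaks also lay within 1000 bp of both mitochondrial ribosomal RNA genes, WBGene00014454 and WBGene00014472. In random placement of the same summits, 6.55 peaks lay near an annotated ribosomal RNA gene, against 5 observed (permutation p = 0.824). The 4 tRNA genes named by the strongest peaks were also mitochondrial, WBGene00014473 near the ND5 peak and WBGene00014458, WBGene00014459 and WBGene00014460 near the ND2 peak.

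**Figure D1:**
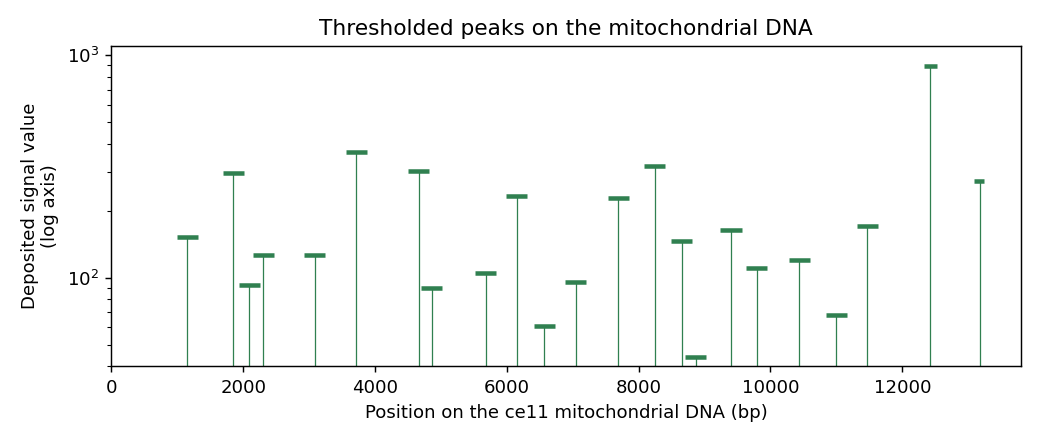
Each bar is a thresholded peak on the mitochondrial DNA, drawn from its start to its end in bp (horizontal axis) at its deposited signal score (vertical log axis), with a thin line at the summit. The 23 peaks are spread along the circle and reach a score of 891 at the peak in ND5.

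On the nuclear chromosomes, 33 of the 73 thresholded peaks lay on X. This was 45.2% (95% confidence interval 33.5 to 57.3) against 17.7% of the nuclear sequence, a 2.56-fold excess (exact binomial test, two-sided, adjusted p = 1.02e-07). In the pooled list X held 21.6% of the 607 nuclear peaks, a 1.22-fold excess (exact binomial test, adjusted p = 0.0142). By the thresholded list, X carried 1.86 peaks per Mb. The autosomes carried between 0.286 peaks per Mb on IV and 0.654 on II. The share of X in the full replicate 1 list was 19.3%, and in the full replicate 2 list 17.5% of the nuclear peaks. By the same exact test, it was 28.1% in the 96 strongest peaks of replicate 1 alone (adjusted p = 0.0211) and 32.8% of the nuclear peaks among those of replicate 2 alone (adjusted p = 0.00657). Of the 40 autosomal peaks, 21 lay outside the middle of the chromosomes (52.5%), in the first or last of 3 equal parts, where 66.7% were expected by length (exact binomial test, adjusted p = 0.0652, which did not pass 0.05). By the same exact test, the shortfall passed in the 96 strongest peaks of replicate 1 alone (53.6%, adjusted p = 0.0291), in those of replicate 2 alone (48.9%, adjusted p = 0.0166) and in the pooled list (55.7%, adjusted p = 1.28e-06).

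**Figure D2:**
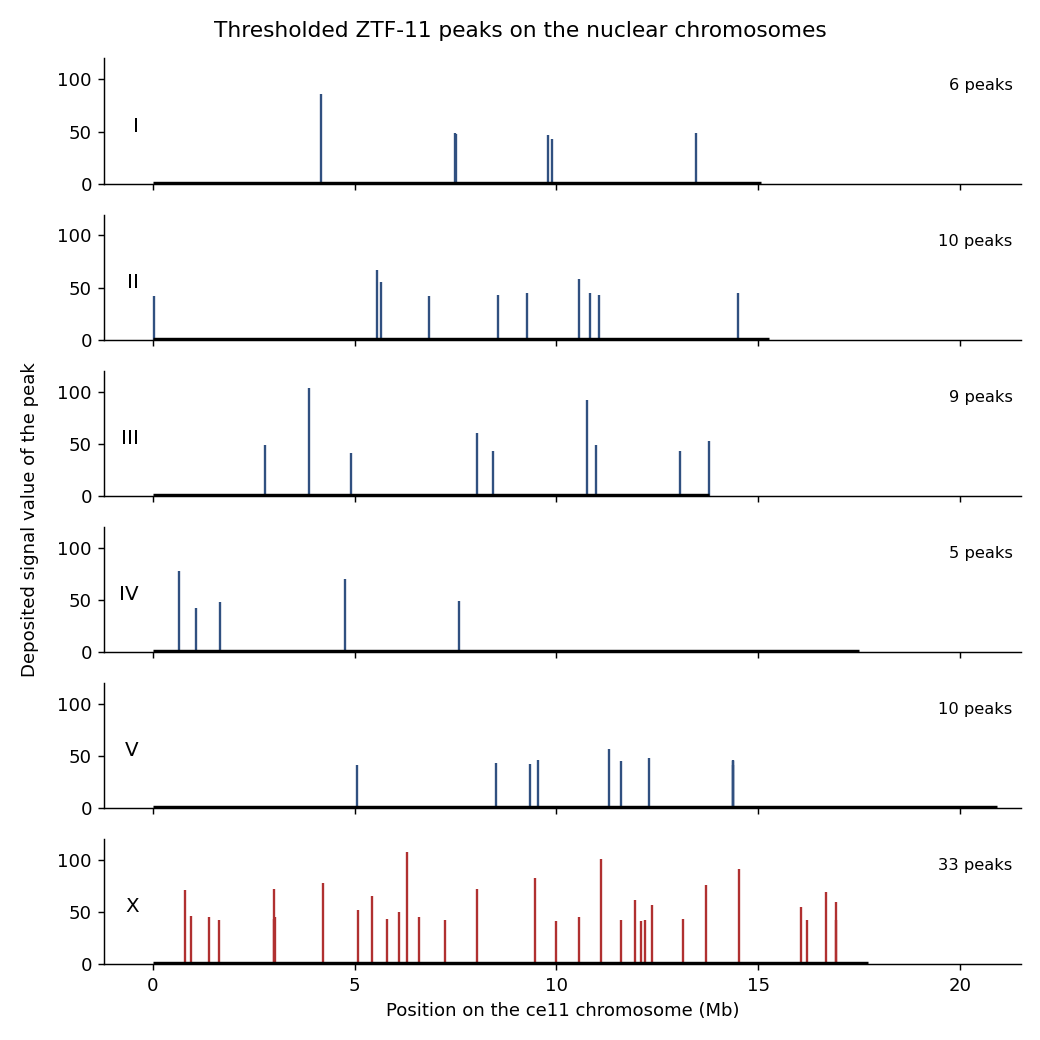
Vertical lines mark the 73 nuclear thresholded peaks at their summits in Mb along each ce11 chromosome (horizontal axes), with heights showing the deposited signal score. X, in red, holds 33 peaks and the autosomes, in blue, hold 5 to 10 each.

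The strongest nuclear peak, rank 17 in the whole list, lay at X 6296392 to 6296711 in an intron of mom-1, which encodes a protein needed for Wnt secretion. Its signal score was 107 and its rank was 1 in replicate 1 and 44 in replicate 2. The nearest protein-coding 5′ end was that of cest-16 (WBGene00020330), 3390 bp away. The next was the peak 265 bp upstream of rpl-3 (WBGene00004414), a gene of the large ribosomal subunit, at III 3867429 to 3867748 with a score of 103. It was followed by intergenic X 11094031 to 11094350, 3995 bp from W02H3.3, at rank 20 of the whole list. The peak 63 bp upstream of tasp-1 (WBGene00010480) at III 10759084 to 10759403 had a score of 91.4, and intergenic X 14525725 to 14526044, 704 bp from nspc-17, had 90.8. These were the nuclear peaks among the strongest 25. The peaks that followed, named after their values were seen, included one at I 4172077 to 4172396 in sls-2.4, a gene of the SL2 spliced leader RNA, with a score of 85.7. Further ones lay upstream of rpl-15 (score 77.9), 4902 bp from the sex determination gene xol-1 on X (score 72.2) and upstream of cdc-48.1 (score 58.2).

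The position of the peaks relative to genes was examined next. Of the 96 summits, 33 lay within 500 bp of the 5′ end of a protein-coding gene (34.4%, 95% confidence interval 25 to 44.8), against 30.5% in random placements (two-sided permutation p = 0.414). The share was 21.9% against 17.8% in the 96 strongest peaks of replicate 1 alone (permutation p = 0.362), 44.8% against 33.8% in those of replicate 2 alone (permutation p = 0.0106) and 26.9% against 20.4% in the pooled list (permutation p = 0.0002). Intron sequence held 11 summits (11.5%), against 22% in placements (adjusted permutation p = 0.0264), and was the class in which the share differed from placement. This call was lost with the stronger 48 peaks, at 8.33% against 15.7% in placements (adjusted permutation p = 0.461), and with the 61 peaks found in both replicates, at 14.8% against 28.7% (adjusted permutation p = 0.0736). The ratio to placement was 0.521 in the main set and 0.532 and 0.514 in these subsets. Exons held 24% against 24.9% (adjusted permutation p = 0.932) and intergenic sequence 30.2% against 22.6% (adjusted permutation p = 0.177). On the mitochondrial DNA, 16 of 23 summits lay near a 5′ end, against 71.4% in placements (permutation p = 0.989). With the nuclear peaks alone, chosen after seeing the data, 17 of 73 summits were near a 5′ end (23.3%) against 17.6% (permutation p = 0.263). When the 5′ ends of genes of every type were counted, the share was 66.7% of the 96 summits against 42.5% in placements (permutation p = 0.0002, the smallest that 10000 placements can give in a two-sided test). Against replicate 1 peaks outside the thresholded list, of which 20.2% lay near a 5′ end, the share of 34.4% was higher (permutation p = 0.002), while the nuclear peaks alone were not distinguished from them (23.3%, permutation p = 0.599).

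Autosomal and X peaks differed in this respect, a contrast that was added after the data were seen. On the autosomes, 16 of 40 summits lay within 500 bp of a protein-coding 5′ end (40%, 95% confidence interval 24.9 to 56.7), 2.02 times the placement value of 19.8% (permutation p = 0.0042). On X, 1 of 33 did (3.03%, 95% confidence interval 0.0767 to 15.8), against 15% in placements (permutation p = 0.0656). That peak lay 96 bp upstream of hsp-3, which encodes an HSP70 chaperone of the endoplasmic reticulum. The shares on X and the autosomes differed from each other with Fisher's exact p = 0.000171, two-sided. Autosomal promoter peaks included those of the ribosomal protein genes rpl-3, rpl-15 and rps-28, of the histone gene his-37 and of cdc-48.1, a gene for an AAA ATPase.

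The X peaks also carried a sequence that autosomal peaks rarely had. GCGCAGGG, the core of the motif at recruitment sites of the dosage compensation complex on X of C. elegans, was counted after the X excess had been seen. It lay within 100 bp of 10 of the 33 X summits (30.3%, 95% confidence interval 15.6 to 48.7) and in 0 of their flank windows (exact McNemar p = 0.00195, two-sided). It lay at 1 of the 40 autosomal summits (2.5%, Fisher's exact p = 0.00174 against X) and at 0 of the 23 mitochondrial summits. Of the 16 stronger X peaks 9 carried it, and of the 17 weaker ones 1 (Fisher's exact p = 0.0024). This split was made after the order of the peaks had been seen, so its p is not independent evidence of a difference. The carriers included the peak in mom-1, that in pks-1, that nearest to xol-1 and 2 overlapping peaks in an intron of Y41G9A.17. The windows around these 2 summits, 2997087 and 2997289, did not overlap, so each held a GCGCAGGG of its own. Both peaks lay at the same peak of replicate 1 (rank 56) and of replicate 2 (rank 31), so they are not independent. Among the 33 strongest X peaks of each replicate alone, 8 in replicate 1 and 9 in replicate 2 carried it.

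**Figure D3:**
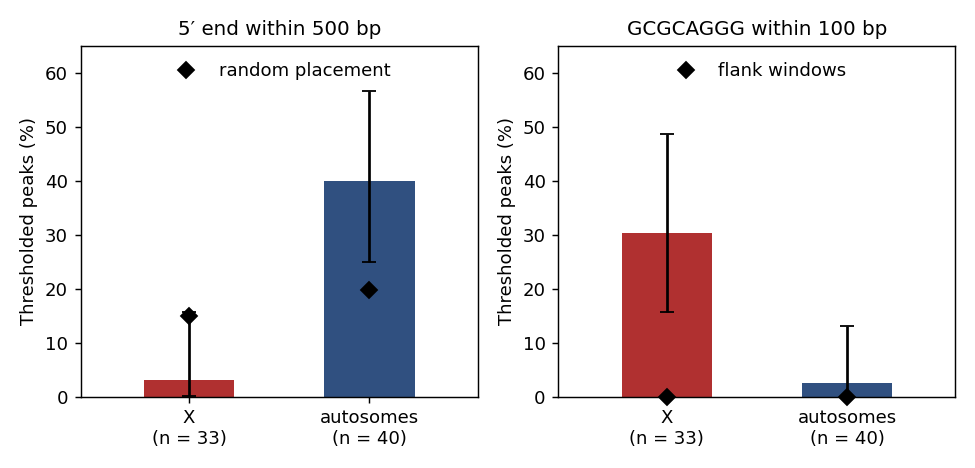
Bars give the percentage of X (red, 33) and autosomal (blue, 40) thresholded peaks with a protein-coding 5′ end within 500 bp of the summit (left) and with GCGCAGGG within 100 bp (right), with exact 95% confidence intervals, and black diamonds give random placement (left) or flank windows (right). The promoter share is 3.03% on X and 40% on the autosomes, and the share with GCGCAGGG is 30.3% and 2.5%.

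Of the 37 gene lists, 11 had a thresholded peak within 1000 bp of the 5′ end of a member, and 7 exceeded random placement after adjustment. Peaks near snoRNA genes, whose products guide modification of other RNAs, numbered 10 against 0.403 in placements (24.8-fold, adjusted permutation p = 0.000925). Some of these snoRNA genes lie within protein-coding genes: K11H12.12 and K11H12.13 in rpl-15, C06A1.9 in cdc-48.1 and F54C9.12 in iff-2. Their peaks lay 342, 148 and 125 bp upstream of the 5′ ends of these protein-coding genes. The rpl-15 peak counts in the ribosomal protein list too, so the 2 lists are not separate. Peaks near snRNA genes numbered 3 against 0.108 (27.8-fold, adjusted permutation p = 0.00247), near microRNA genes 3 against 0.364 (8.23-fold, adjusted permutation p = 0.0312) and near other noncoding RNA genes 24 against 9.75 (2.46-fold, adjusted permutation p = 0.00148). Peaks near tRNA genes numbered 29 against 20.9 (1.39-fold, adjusted permutation p = 0.000925). The calls of the tRNA and other noncoding RNA lists were lost with the stronger 48 peaks, at 20 against 19.4 and 4 against 3.76 (adjusted permutation p = 1 for both), and with the nearest gene (adjusted permutation p = 0.499 for both). On the nuclear chromosomes alone there were 9 peaks near tRNA genes against 1.07 (8.43-fold, adjusted permutation p = 0.000617). Of these 9, 6 had a further copy in the nuclear genome of sequence within 100 bp of the summit. The 3 without one were 3.45 times the number in placements without one (one-sided permutation p = 0.0534). Their nearest tRNA 5′ ends lay 346, 82 and 892 bp from the summit, against 20 to 64 bp for the 6 with a copy. At these 3 the searched window took in little or none of a tRNA gene. The split thus does not separate tRNA genes with and without copies. Ribosomal protein genes had 4 peaks against 0.0777 (51.5-fold, adjusted permutation p = 0.000925), and heterochronic genes, which time larval cell fates, had 3 against 0.0397 (75.6-fold, adjusted permutation p = 0.000925). The heterochronic and microRNA calls were also lost with the stronger 48 peaks, at 0 peaks each. With the nearest gene they had 1 and 2 peaks (adjusted permutation p = 0.499 for both). The peaks at mir-48 and mir-241, with summits at V 14365057 and 14366743, are neighbours and count in both of these lists.

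Compared with draws from the 19264 genes near a replicate 1 peak, 6 of these 7 lists stood out. The snoRNA list had 12 genes near a thresholded peak against 1.38 expected (adjusted exact hypergeometric p = 5.03e-07) and the tRNA list 13 against 2.46 (adjusted p = 2.01e-05). The ribosomal protein list had 4 against 0.401 (adjusted exact p = 0.00432), the snRNA list 4 against 0.378 (adjusted exact p = 0.00413), the heterochronic list 3 against 0.110 (adjusted exact p = 0.00162) and the microRNA list 6 against 0.820 (adjusted exact p = 0.00162). Of these 6 microRNA genes 4 lay at 1 peak, which was not found in replicate 2, so they are not independent. The 13 tRNA genes lay at 9 peaks, the 12 snoRNA genes at 10 and the 4 snRNA genes at 3. Genes of these lists are thus not independent draws either. With the peaks found in both replicates, microRNA genes had 2 peaks and did not pass in placement (adjusted permutation p = 0.194) or in gene draws (adjusted exact p = 0.679). Other noncoding RNA genes, with 35 against 25.8, did not pass (adjusted exact p = 0.146). Against random placement of the 96 strongest peaks of each replicate alone, the ribosomal protein and snoRNA lists passed in both, the snRNA and other noncoding RNA lists in replicate 1, and the tRNA, heterochronic and microRNA lists in neither. Against draws from genes near a replicate 1 peak, the snoRNA and snRNA lists passed in both, the other noncoding RNA list in replicate 1, the ribosomal protein and tRNA lists in replicate 2, and the heterochronic and microRNA lists in neither. Heterochronic and microRNA genes had 1 peak each in replicate 1 alone and 0 in replicate 2 alone, and neither list passed with a distance of 500 bp (adjusted permutation p = 0.119 and 0.102).

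**Figure D4:**
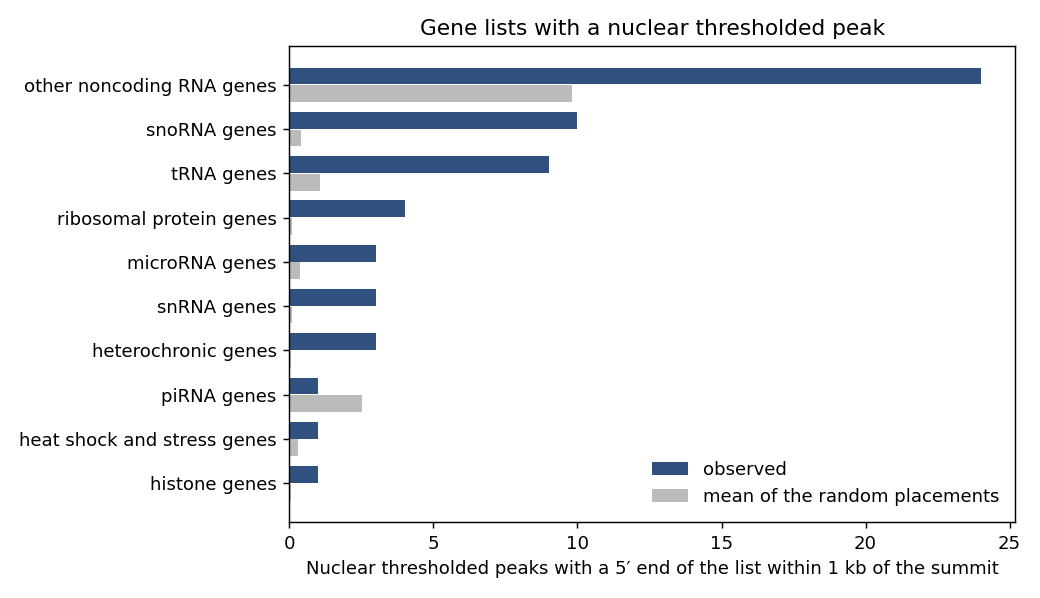
Bars give the number of the 73 nuclear thresholded peaks with the 5′ end of a list gene within 1 kb of the summit (blue) and the mean of 10000 random placements (grey), for the lists with 1 or more such peaks. The snoRNA list has 10 peaks against 0.409 and the tRNA list 9 against 1.07.

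The ribosomal protein genes with peaks were rpl-3, rpl-15, rpl-20 (peak 275 bp upstream, at IV 4749893 to 4750212, score 70.2) and rps-28 (peak 461 bp upstream, at IV 1659070 to 1659389, score 48.1). The summit near rpl-20 lay closer to the 5′ end of Y17G9B.5, at 187 bp. The snoRNA genes at the strongest peaks were K11H12.13 and K11H12.12, both near the rpl-15 peak on IV, C06A1.9, near the cdc-48.1 peak on II, and T03F7.8, 54 bp from a summit on V with a score of 56.7. The snRNA genes were sls-2.4 on I, sls-2.2 and sls-2.3 at 1 peak on II (score 67.4) and R07E5.16 on III (score 48.7). Among other noncoding RNA genes, R12E2.18 overlapped the sls-2.4 peak, C17C3.23 and C17C3.22 lay at the sls-2.2 peak, and C18A11.13 lay 263 bp from the X peak nearest to xol-1. The heterochronic genes were mir-48 and mir-241, members of the let-7 microRNA family, with summits 548 bp and 460 bp upstream of the annotated 5′ ends on V (scores 45.2 and 45.9), and nhl-2, a cofactor of microRNA function on III (score 41.6). The summit near nhl-2 lay 835 bp from its 5′ end, closer to that of tag-340, at 588 bp, and inside the noncoding RNA gene F26F4.14. That peak ranked 26 in replicate 1 and 1421 in replicate 2. The microRNA list added mir-54, mir-55, mir-55b and mir-56 at 1 peak on X (score 43).

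Histone genes had 1 peak, at his-37, against 0.0513 (permutation p = 0.0504, adjusted p = 0.233). Heat shock and stress genes had 1, at hsp-3, against 0.305 (adjusted permutation p = 1). piRNA genes had 1, at 21ur-13318 on I, against 2.53 (adjusted permutation p = 1). The other 26 lists had 0 of the 96 peaks, and their placement means ranged from 0.0283 for neurotransmitter identity genes to 2.38 for pseudogenes. They included neuronal lists and the Notch pathway, with placement means of 0.0758 for proneural and neurogenesis factors, 0.0525 for pan-neuronal genes, 0.0628 for terminal selectors, 0.245 for neuropeptide genes and 0.0456 for Notch pathway genes. With these means under 1, a depletion of these lists was not detectable with 96 peaks. The further lists without a peak were those of bHLH, ceh homeobox, nuclear hormone receptor, other zinc finger, neuronal ion channel and chemoreceptor genes. They also comprised epidermal, collagen, muscle, intestinal, germline, glial, vulval, major sperm protein, Wnt, cell cycle, DREAM complex, translation housekeeping and long noncoding RNA genes.

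The AAGTTT core was found within 100 bp of 13 of the 96 summits (13.5%, 95% confidence interval 7.41 to 22) and in 25 of the flank windows (26%). The motif was in the peak alone at 10 peaks and in the flank alone at 22 (exact McNemar p = 0.0501, two-sided), so peak summits did not carry more of the core than their surroundings. Among the 96 strongest peaks of replicate 1 alone, 7.29% carried it against 34.4% of flanks (exact McNemar p = 6.16e-06). In those of replicate 2 alone, 21.9% did against 29.2% (exact McNemar p = 0.296), and in the pooled list 19.3% against 28.8% (exact McNemar p = 5.83e-05). On X, 4 of 33 summits carried AAGTTT against 16 flank windows (exact McNemar p = 0.00754), while on the autosomes 5 of 40 did in both. The GC content around the nuclear summits was 45.1 ± 7.04% (SD over 73 windows) and around the mitochondrial summits 24.8 ± 4.64% (SD over 23 windows). Against promoter positions matched on GC content, 13.5% compared with 24% (exact McNemar p = 0.0987).

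The ztf-11 locus, taken to be present in extra copies in the transgene of the strain, was examined in every list. No thresholded peak lay within 20 kb of ztf-11 (WBGene00009939, I 9904303 to 9910545) or of unc-119 (WBGene00006843, III 10902641 to 10908935). The numbers expected from the density of that list were 0.0185 and 0.0303, so these counts of 0 show no depletion. In the single replicates the region of ztf-11 did stand out. Replicate 1 had 26 peaks there against 13.9 from the density on the rest of the chromosome (1.86-fold, permutation p = 0.0024), and replicate 2 had 13 against 0.945 (13.8-fold, permutation p = 0.0001). The pooled list had 8 against 0.271 (29.5-fold, permutation p = 0.0001, the smallest 10000 placements can give). Within ztf-11 itself lay 6 of the 26 replicate 1 peaks, 2 of the 13 replicate 2 peaks and 1 of the 8 pooled peaks. The strongest peak of the region lay in the gene in each replicate alone, in an exon at position 9907190 in replicate 1 (rank 23, score 32.4) and in an intron at 9906760 in replicate 2 (rank 60, score 29.9), while the strongest in the pooled list lay outside it at 9894952. The region of unc-119 had 11 replicate 1 peaks against 14 (permutation p = 0.825), 0 replicate 2 peaks against 1.10 and 0 pooled peaks against 0.371. These lists thus gave no sign of extra copies that map to unc-119.

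The lists on ce10 were close in number to those on ce11, at 30000 for replicate 1, 2058 for replicate 2, 604 for the pooled list and 103 for the thresholded list. All 96 thresholded ce11 peaks had a ce10 peak on the same chromosome with a signal score within 0.01. The 7 thresholded peaks listed on ce10 alone had scores from 40.7 to 41.0, at the lower end of the list.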

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

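The nuclear peaks alone, also against replicate 1 peaks, and the peaks found in both replicates were chosen after seeing the data, as was the pooled list for the gene lists. Over all results and alternatives, 121 values kept their direction and their side of the threshold or moved little, 18 weakened, 13 became stronger, 6 moved and 7 changed direction, which includes counts of 0 where under 1 was expected. The replicate overlap, the sharing of the strongest peaks and the X excess kept their direction and side of the threshold under every alternative run, although the X share fell from 45.2 to 21.6% with the pooled list, 1.22-fold above its share of the sequence. At thresholded peaks the rank correlation was 0.0318, not directly comparable with 0.241 over all pairs, since these pairs were selected by pooled signal. With summits within 100 bp, 78.1% of thresholded peaks were found in replicate 2; of nuclear peaks, 100% were found in replicate 1. The promoter share passed the threshold with the pooled list (26.9% against 20.4% in placements) and with 5′ ends of all genes (66.7% against 42.5%). It passed against replicate 1 peaks (34.4% against 20.2%), but not with nuclear peaks alone (23.3%, permutation p = 0.599). In the strongest peaks of 1 replicate alone it was 21.9% against 17.8% in replicate 1 and 44.8% against 33.8% in replicate 2. The promoter feature class was likewise above placement in replicate 2 alone. Mitochondrial placements lay near a 5′ end in 71.4%, and replicate 1 listed 0 mitochondrial peaks. Shares of lists with unlike mitochondrial content are thus not directly comparable. The intron share lost its call with the stronger 48 peaks (8.33%) and with peaks found in both replicates (14.8%), where fewer peaks were tested. The share of autosomal peaks outside the chromosome middles passed with the pooled list (55.7%) and in 1 replicate alone (48.9 to 53.6%). The number of gene lists called was 3 with the stronger peaks, 3 with the nearest gene and 2 to 4 in 1 replicate alone; heterochronic and microRNA genes had 0 peaks among the stronger 48 and 0 to 1 in 1 replicate alone. The AAGTTT share lay below the flanks at 4.17% with 50 bp windows, 40.6% for AAGTT, 14.8% with peaks found in both replicates, 19.3% with the pooled list and 7.29 to 21.9% in 1 replicate alone, the call being that of replicate 1. The number of peaks near ztf-11 was 1 within 40 kb and 13 to 26 in the single replicates. Leaving out peaks near the transgene loci removed no peak and so tested nothing. The cause of these changes was not tested. The depth of both libraries is unknown, which limits what the difference in peak numbers can show. No paired analysis was possible because there was 1 group.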

Other observations

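The tests of mitochondrial coverage, of X among weaker peaks, and of peaks without a further copy of their sequence were chosen after the results were seen, as was the use of the pooled list; the tests without a copy were added when the share of peaks with a copy, fixed first, had not decided. The relaxed pooled list of 631 peaks, examined for the gene lists, gave 10 lists above placement. The snoRNA list had 40 peaks against 3.94 (adjusted permutation p = 0.000529), the tRNA list 70 against 27.2 and the ribosomal protein list 17 against 0.968, each with the same adjusted p. Histone genes had 3 against 0.45 (adjusted permutation p = 0.037), DREAM complex genes 3 against 0.298 (adjusted permutation p = 0.0164) and collagen and cuticle genes 8 against 2.26 (adjusted p = 0.00647), of which histone genes alone also exceeded draws from genes near replicate 1 peaks (adjusted exact p = 0.039). Proneural and neurogenesis factors had 0 peaks against 0.518, bHLH genes 0 against 0.309, Notch pathway genes 0 against 0.32 and pan-neuronal genes 1 against 0.416 (adjusted permutation p = 0.834). Neuronal ion channel genes had 1 peak against 3.17 and pseudogenes 7 against 22.2.

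The excess of peaks on X was weighed against 3 explanations. X held 19.3% of the replicate 1 peaks ranked below 1000 (95% confidence interval 18.8 to 19.7), above its 17.7% of the sequence. The bound set against more X-derived reads as the whole source was 25%. These peaks are nearly the full replicate 1 list, whose X share was already known, so falling under that bound decides nothing. A contribution of such reads stays open. For repeated sequence, copies (50 bp or longer at 95% identity) were sought of the sequence within 100 bp of each summit. The share of X peaks with a further copy was 15.2% against 11.8% of random positions. Its 95% confidence interval (5.11 to 31.9) lay neither above 50% nor below 25%, as had been required to decide. Among the 65 nuclear peaks without a copy X still held 43.1% (exact binomial p = 1.69e-06). With a copy at 8 of the 73 nuclear peaks, this outcome was fixed by that number and is no separate test. It shows that copies of these windows at this identity were too few to be the whole source of the excess. The X motif, with exact McNemar p = 0.00195 against flank windows, is consistent with a candidate explanation in which part of the X signal came from sites of the dosage compensation complex. Whether ZTF-11 itself binds there, or such sites are recovered with other factors too, was not tested, since no other factor and no untagged strain was analysed here.

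Uneven coverage of abundant mitochondrial DNA in the replicate 2 library stays open for the mitochondrial peaks. The 29 mitochondrial peaks of that library covered 58.1% of the mitochondrial DNA, against 0.721% of the nuclear genome in its nuclear peaks, and replicate 1 listed none, though a mitochondrial filter on that replicate cannot be excluded from its list. The coverage decides nothing, because the thresholded peaks that prompted the test already covered 48.2%. AAGTTT sites gave no sign of binding through the core motif, since 4 of 23 mitochondrial summits had 1 nearby against 7.38 in random placement (one-sided permutation p = 0.966). Nuclear summits had no excess of the core over their flanks either (12.3% against 24.7%), so the core cannot tell binding from an artifact here. The mitochondrial content of the libraries and of the control was not analysed here, and no biological explanation was tested.

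Peaks at tRNA, snoRNA and snRNA genes were weighed against repeated sequence and a general background. Of these 21 nuclear peaks, 38.1% had a further copy in the genome, against 11.8% of random positions; its 95% confidence interval (18.1 to 61.6) did not decide, nor did those of the 9 peaks at tRNA genes (66.7%, 29.9 to 92.5) and the 12 others (16.7%, 2.09 to 48.4) when the classes were then split. The peaks without a copy were next compared with placements that also had none. The 3 at tRNA genes were 3.45 times the placed number (permutation p = 0.0534), too few to decide on shared reads. Of these 3, 1 also lay 51 bp from the snoRNA gene ZK994.7 and was counted with the tRNA genes only. The 10 at snoRNA or snRNA genes without a tRNA gene nearby were 23.1 times the placed number (permutation p = 0.0001, the smallest 10000 placements can give). As 2 of those 12 peaks had a copy, this largely repeats the excess already seen. It shows that shared reads with copies of the searched windows were not the whole source there. Copies of sequence farther from these summits were not searched. Weaker replicate 1 peaks lay near these genes 1.43-fold above placement, against 13.4-fold for the nuclear thresholded peaks, which fell between the bounds set for a general background at RNA genes. That background and binding by ZTF-11 cannot be told apart here, because no other immunoprecipitation was analysed.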
